A study of Drosophila melanogaster with 42 samples.

How the data were processed

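The data are 42 two-colour spotted arrays of RNA from the head and thorax of male flies, 21 of Indy206 heterozygotes and 21 of matched heterozygous controls, at 8 ages. Per the labels' protocols, flies were dissected on a cold block, RNA came from replicates of 15 males homogenized in Trizol, and it was amplified in 1 linear round with T7 polymerase. The sample carried Cy5 and the reference Cy3, per the labels, and no dye swap is listed, so a dye effect of a spot stays in its level and cancels between groups. The replicates are separate samples of flies.

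The deposited values are log2 ratios, 1 per spot and array, processed by the authors with limma, per the submitters' processing notes, which give no version. The background correction, the normalization within arrays, any filter of spots, the log base and the direction are not given in the sources used here. The direction was read as sample over reference and the base as 2, which is the convention of limma for Cy5 over Cy3, and is called likely. The sign of every difference and slope rests on that reading. Array medians ran from -0.014 to 0.0019, so the values were taken as already normalized and were not normalized again. Interquartile ranges ran from 0.19 to 0.38 and single values from -7.28 to 5.93. No value was missing, and the lowest correlation between arrays was 0.51. Signal over background was not analysed here.

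Spots were named from the platform annotation: 10827 spots had 1 gene, 227 had several and 8946 had none paired here. Of the 1-gene spots 10823 matched the gene table of the assembly Release 6 plus ISO1 MT, which served for names and for which genes neighbour each other. Spots of 1 gene were averaged (793 genes had more than 1), and spots with several genes or none were tested as single units without a name. This gave 19077 units.

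A linear model with 16 group means was fitted to all arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 26 residual degrees of freedom. The contrasts were the mean over ages of Indy206 minus control, the same difference at each age, the least-squares slope on day in each genotype per 10 days, their mean and their difference. P-values were adjusted by Benjamini-Hochberg within each contrast and called under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

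Of 29 gene lists, fixed before the data were examined, 28 with at least 3 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. They cover the respiratory chain complexes, ATP synthase, the TCA cycle, glycolysis, fatty acid oxidation, fatty acid synthesis and lipid storage, insulin and FOXO signalling, immune effectors, heat shock proteins, antioxidant enzymes, the circadian clock, ribosomal proteins of the cytosol and mitochondria, the proteasome, cytochrome P450 enzymes and glutathione S-transferases. Marker lists cover photoreceptors, muscle, neurons, odorant-binding proteins, fat body, yolk proteins, midgut, accessory gland, testis and haemocytes. The Turandot list had 1 measured member, TotB, and was not tested. Several other lists were measured in part. Single-gene spots covered 21 of 34 fixed members of complex I, 8 of 14 of complexes II and III and 8 of 9 of complex IV. They covered 10 of 24 immune effectors and 7 of 15 inducible heat shock proteins, with none of the Hsp70 genes.

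Genes were named by a rule fixed before the data were examined. For genotype these are Indy and, among called genes, the 12 highest and 12 lowest with the same sign at all 8 ages, filled up with those at 7, and with bare CG numbers used only where fewer other symbols existed. For age they are the 12 steepest called slopes on each side with the same sign in both genotypes. At each age they are the highest and lowest called gene, for the difference in slope the 3 smallest p-values as none was called, and for each list up to 4 members with the smallest p. Cyp6a14, COX7C and other list members come from that last part.

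The model was tested on simulated data with the real spread of each of 19077 units. For genotype differences of 0.5 it called 98 percent of the higher and 98 percent of the lower changed units. For slopes over both genotypes of 0.1 per 10 days it called 94 percent of the rising and 90 percent of the falling units. In the same simulation a shift of -0.15 in complex I was called by camera and no other list was, while fry called 1 other list. The simulated units were independent of each other, so this does not show how often lists of correlated genes are called by chance.

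Alternatives covered the scaling of arrays, averaging of spots, array weights, robust variance, replicate numbers, the model for age, single ages, a minimum size, the list test and each array left out in turn. Others were chosen after seeing the data: tests on 1-gene spots only, a covariate made of the testis and accessory gland medians of each array, and the exclusion of 2 arrays that stand apart in the principal components. The covariate was lower at day 80 than at day 5 in both genotypes, so it also takes up change with age.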

Results

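Transcripts of the head and thorax of adult male Drosophila melanogaster were measured at 8 ages between day 5 and day 80 in 2 genotypes. Indy206 flies carry an altered copy of Indy (I'm Not Dead Yet), which encodes a citrate transporter of the plasma membrane, over a Canton-S chromosome; reduced Indy activity is known to lengthen fly life span. The controls were matched heterozygotes of a control line over Canton-S. There were 42 two-colour arrays, 21 per genotype, each comparing 1 sample of pooled males with a common reference made from control RNA of all ages. Each of the 16 groups held 2 or 3 arrays. The comparisons address how gene expression changes with age and whether the long-lived genotype differs from the controls. Values are log2 ratios of sample over reference for 20000 spots, tested as 19077 units, of which 9904 are single genes and the others are spots without a single paired gene. Replicates are RNA from separate sets of 15 males, so the p-values measure differences against the variation between such sets, and the number of arrays per group limits the precision.

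The reference differed from the samples in tissue markers on every array. Testis markers had a mean array median of -2.09 ± 0.61 (SD, n = 42) and accessory gland markers one of -2.95 ± 0.78 (SD, n = 42), and both lists lay below 0 on all 42 arrays. Midgut digestive enzymes lay below 0 on 41 arrays, at -0.87 ± 0.53 (SD, n = 42). Photoreceptor markers lay above 0 on all 42 arrays, at 0.71 ± 0.17 (SD, n = 42), as did odorant-binding proteins of the head, at 0.45 ± 0.18 (SD, n = 42). The testis median ranged from -3.65 to -0.51 between arrays, so the level of these abdominal markers varied from array to array.

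**Figure D1:**
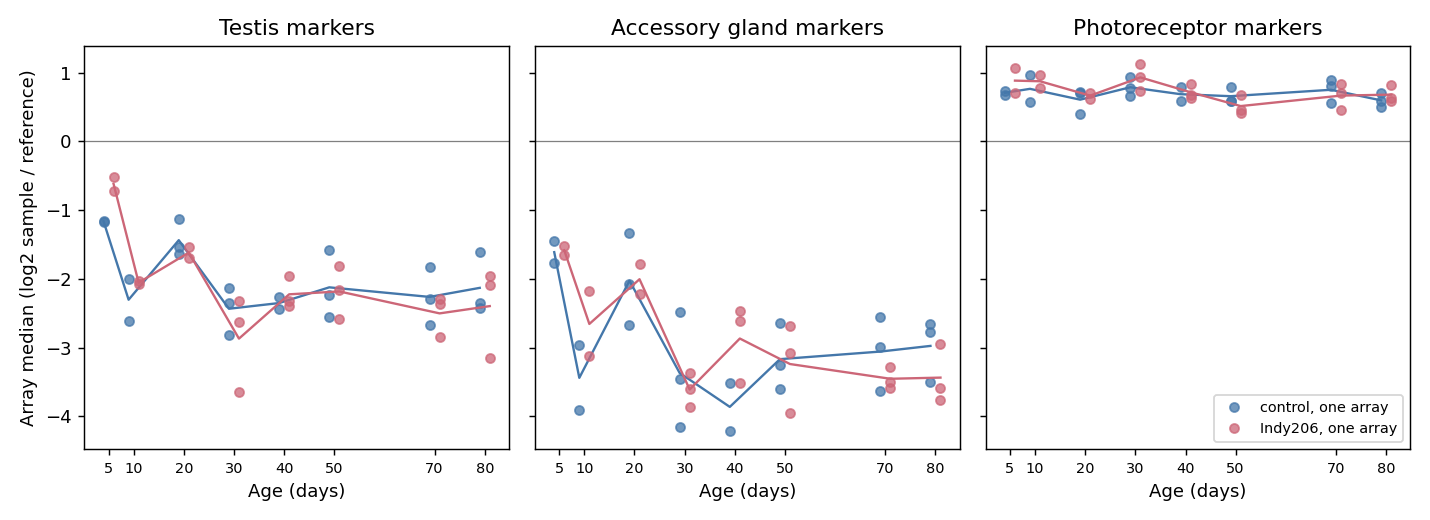
Array medians of the testis, accessory gland and photoreceptor lists (log2 ratio of sample over reference) against age in days, with a point per array and a line through the group means, in controls and Indy206. The testis points lie between -3.65 and -0.51, the accessory gland points between -4.21 and -1.34, and the photoreceptor points between 0.40 and 1.12.

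The Indy transcript itself was lower in Indy206 flies at all 8 ages. The log2 ratio was -1.16 ± 0.27 (SD, n = 21) on the Indy206 arrays and -0.26 ± 0.14 (SD, n = 21) on the control arrays. Averaged over ages the difference was -0.88 ± 0.064 (SE), which leaves 0.543 of the control level (limma adjusted p = 2.0e-10). The highest Indy206 array, at -0.67, lay below the lowest control array, at -0.49. A two-sided permutation test of the genotype labels within ages, with 100000 resamples, gave p = 1e-05, the smallest it can give. The difference ran from -0.54 at day 5 to -1.14 at day 70, and both Indy spots gave the same direction, at -0.90 and -0.86.

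**Figure D2:**
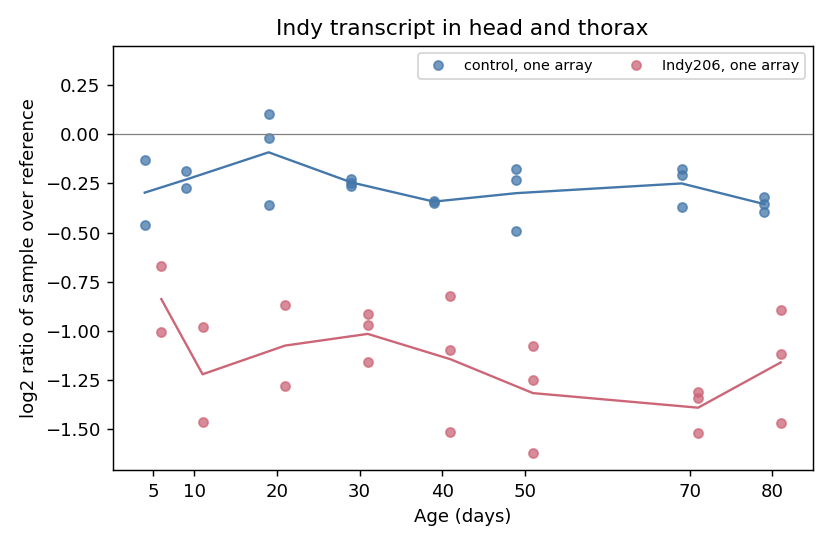
The Indy log2 ratio of sample over reference on each array against age in days, in control and Indy206 flies, with a line through the group means. Every Indy206 point lies at or below -0.67 and every control point at or above -0.49.

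Averaged over all ages, 67 units differed between the genotypes, 25 higher and 42 lower in Indy206, and 50 of them are single genes, 16 higher and 34 lower. Among genes higher in Indy206, CG15818 stood out at 1.66 ± 0.13 (SE) on the log2 scale, a 3.16-fold difference (limma adjusted p = 6.9e-10). GstE1, a glutathione S-transferase, was higher by 0.74 ± 0.085 (SE), and the serine protease gene teq by 0.67 ± 0.094 (SE), with its 3 spots between 0.19 and 0.92. Ctr9, a subunit of the Paf1 transcription elongation complex, was higher by 0.57 ± 0.053 (SE). Herc4, an E3 ubiquitin ligase gene, was higher by 0.24, zda by 0.22 and SPARC, a basement membrane glycoprotein gene, by 0.31. The remaining genes named on this side were CG18180 at 0.75, CG46491 at 0.57, CG18179 at 0.52, CG5160 at 0.40 and CG34195 at 0.24. All of these were higher at all 8 ages except SPARC, higher at 7. The naming rule took genes with the same sign at all 8 ages first, so this is no separate result. CG18179 and CG18180 are adjacent genes, and whether the spot of each also measures the other was not tested.

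On the lower side, lectin-28C, a C-type lectin gene, was lower by the most among named genes, at -0.91 ± 0.12 (SE) and 0.532 of control. The potassium channel gene sand stood at -0.87 ± 0.067 (SE). Also lower were the glutathione S-transferase gene GstE12 at -0.61 ± 0.077 (SE), the cytochrome P450 genes Cyp4d21 at -0.59 ± 0.10 (SE) and Cyp6d2 at -0.56 ± 0.076 (SE), and the carboxylesterase gene alpha-Est2 at -0.52 ± 0.090 (SE). The glutathione S-transferase list was not called (camera adjusted p = 0.15), with GstE1 higher and GstE12 lower. Golgin84, which encodes a Golgi protein, stood at -0.46, the retinol dehydrogenase gene Rdh1 at -0.37 and the cuticle gene TwdlE at -0.32, with its spots at -0.53 and -0.11. The translation factor gene eIF3k stood at -0.24, mino at -0.24 and the aldehyde oxidase gene AOX3 at -0.23. All 12 were lower at all 8 ages, which the naming rule selected for. Called genes lower at 7 ages, such as smp-30 at -0.76 and veil at -0.67, were passed over by it. Leaving out single arrays ended the calls of AOX3, mino, Herc4 and Rdh1 for some arrays, and leaving out days 5 and 10 those of zda, eIF3k, mino and AOX3. SPARC was not called with arrays scaled to a common spread (limma adjusted p = 0.061), nor AOX3 without the 2 arrays that stand apart (limma adjusted p = 0.058), and with a minimum log2 difference of 0.5 the count was 24.

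Averaged over ages, transcripts of oxidative phosphorylation were lower in Indy206 as groups, with small shifts per gene. Of 21 measured genes of complex I, 20 had values below 0, with a median of -0.12 (camera adjusted p = 1.1e-09, and adjusted p = 0.029 with an estimated correlation). ND-42 passed the test over all genes at -0.22 ± 0.051 (SE), and 4 members passed when adjusted over the list alone, among them ND-39 at -0.19, ND-20 at -0.15 and ND-B16.6 at -0.22. All 8 measured genes of complexes II and III lay below 0, with a median of -0.15 (camera adjusted p = 2.6e-06, adjusted p = 0.064 with an estimated correlation). None passed over all genes and 4 passed when adjusted over the list alone, including SdhC at -0.21 and Cyt-c1 at -0.14. Complex IV had 7 of 8 genes below 0 and a median of -0.15 (camera adjusted p = 4.9e-05, adjusted p = 0.076 with an estimated correlation). None of its genes passed over all genes and 3 passed adjusted over the list alone, COX4 at -0.34, levy at -0.16 and COX7C at -0.19. All 13 ATP synthase genes lay below 0, with a median of -0.12 (camera adjusted p = 2.8e-06, adjusted p = 0.064 with an estimated correlation). None passed over all genes and 3 passed adjusted over the list alone, ATPsynD at -0.33, ATPsynO at -0.22 and ATPsyngamma at -0.17. Complex I was the 1 list of 28 called with an estimated correlation, a count that 5 of 100 relabellings of the arrays reached, the real one included. Taken by age, the array medians were lower in Indy206 at 6 of 8 ages for complex I, complex IV and ATP synthase. For complexes II and III they were lower at 5. None of these lists was lower at day 10 or day 80. The median difference over genes at day 10 was 0.076 for complex I, 0.13 for complexes II and III, 0.16 for complex IV and 0.12 for ATP synthase. At day 80 it was 0.026, 0.082, 0.00025 and 0.092 in the same order.

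Other lists shifted by less. Cytosolic ribosomal proteins had a median of -0.070, with 30 of 36 below 0 (camera adjusted p = 0.00014, adjusted p = 0.42 with an estimated correlation), and mitochondrial ribosomal proteins one of -0.021, with 40 of 60 below 0 (camera adjusted p = 0.021, adjusted p = 0.75 with an estimated correlation, and no call without days 5 and 10). No member of either list passed the test, over all genes or adjusted over the list alone. Cytochrome P450 genes had a median of -0.030, with 55 of 79 below 0 (camera adjusted p = 0.00019, adjusted p = 0.11 with an estimated correlation). Cyp4d21, Cyp6d2 and Cyp6a14, the last at -0.54, passed over all genes, and 4 members passed adjusted over the list alone. Proteasome subunits had a median of 0.058, with 23 of 25 above 0 and no member passing the test (camera adjusted p = 7.3e-05, adjusted p = 0.42 with an estimated correlation). Flight and body muscle markers were not called, with a median of 0.055 and 7 of 17 members below 0 (camera adjusted p = 0.48).

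**Figure D3:**
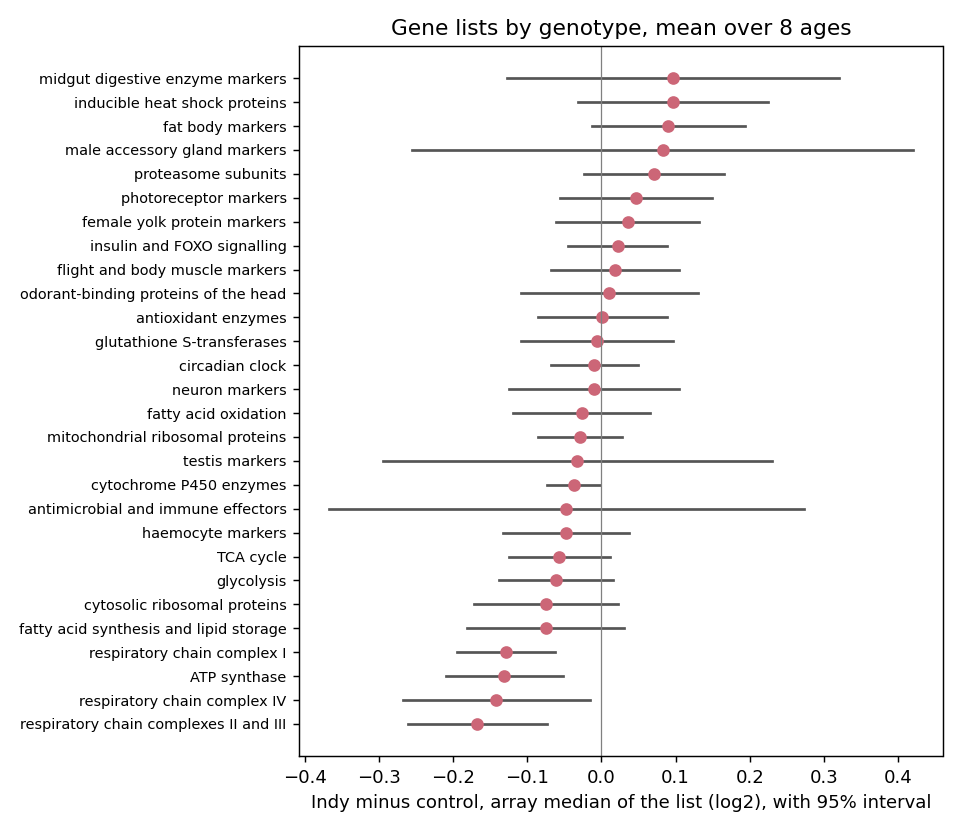
Difference between Indy206 and control flies in the array median of each of 28 gene lists (log2, mean over 8 ages), with 95% intervals from a linear model over the 42 arrays. The intervals of the respiratory chain complexes and ATP synthase lie below 0, and that of the muscle markers runs from -0.068 to 0.10.

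Taken at single ages, the genotypes differed in few units. The counts were 0 at day 5, 1 at day 10, 0 at day 20, 9 at day 30, 13 at day 40, 3 at day 50, 26 at day 70 and 6 at day 80. At unadjusted p under 0.05, limma counted 728 units at day 5, 868 at day 10, 588 at day 20, 899 at day 40 and 920 at day 50. Each of these is fewer than the share of 0.05 of 19077 units that chance alone would pass. At days 30, 70 and 80 it counted more, 1243, 1770 and 1079. CG15818 was the highest called gene at day 30 (2.76), day 40 (2.03) and day 70 (1.86). The lowest was sand at days 30 (-0.90) and 80 (-1.18), CG14356 at day 40 (-1.21), Indy at day 50 (-1.02) and Cyp4d21 at day 70 (-1.80 ± 0.27 SE). Ctr9 was highest at day 50 (0.81), and FeCH, which encodes the heme enzyme ferrochelatase, at day 80 (0.64 ± 0.11 SE). The 58 calls summed over ages became 2 when each age was fitted alone, which ended every named call here except CG15818 at day 30, and were 148 with quantile normalization and 123 with array quality weights. Which age has calls depends on the scaling: with quantile normalization there were 68 at day 5, 27 at day 20 and 6 at day 70. In the main processing, the calls summed over ages were 163 without control day 70 replicate 3 and 39 without control day 70 replicate 2. The loss of some single array ended the calls of sand at days 30 and 80, CG15818 at days 40 and 70, Ctr9 and Indy at day 50 and FeCH at day 80.

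With age, immune effector transcripts rose in both genotypes. Slopes are log2 units per 10 days, as the mean of both genotypes. Def, which encodes the antimicrobial peptide defensin, rose by 0.41 ± 0.033 (SE), the diptericin gene DptB by 0.40 ± 0.044 (SE), the attacin genes AttD and AttB by 0.38 and 0.37, and Mtk, the metchnikowin gene, by 0.27 ± 0.050 (SE). In controls Def went from -1.59 at day 5 to 1.86 at day 80, and in Indy206 from -1.24 to 1.79. The serine protease homologue SPH93 had the steepest named rise, 0.51 ± 0.045 (SE), followed among other genes by the serpin Spn88Eb at 0.33 and the phagocytic receptor NimC4 at 0.29. Also rising were mah at 0.27, RnrL, the large subunit of ribonucleotide reductase, at 0.24, GstD3 at 0.24 and Neurochondrin at 0.24. Of 10 measured antimicrobial and immune effectors, 9 rose and none fell over all genes, and all 10 rose adjusted over the list alone, with a median of 0.24 (camera adjusted p = 3.0e-13, adjusted p = 0.0059 with an estimated correlation).

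Several muscle and male reproductive genes and the storage protein gene Lsp2 fell with age. Lsp2, a storage protein gene of the fat body, fell by 0.51 per 10 days, the troponin C gene TpnC4 by 0.43 and the flight muscle gene fln by 0.27. SERCA, the calcium pump of the sarcoplasmic reticulum, fell by 0.35, the neuropeptide-like gene Nplp3 by 0.41 and the corneal lens gene retinin by 0.30. The sperm gene Mst98Cb fell by 0.46, and the seminal fluid genes Mst57Dc, aqrs and Acp36DE by 0.35, 0.31 and 0.26, beside the serpin Spn77Bb at -0.26. The unit asRNA:CR11538 had a slope of -0.45, and its spot may not tell this antisense RNA from the gene on the other strand. Mst98Cb, Mst57Dc, aqrs, Acp36DE and Spn77Bb lay between -2.50 and -4.40 on average in controls, far below the reference. In controls at day 5, however, Mst98Cb stood at 0.27, Mst57Dc at -0.049 and aqrs at -0.052, against -3.94, -3.34 and -2.83 at day 80. Acp36DE and Spn77Bb were already low in controls at day 5, at -2.72 and -1.99. With the level of the testis and accessory gland markers as a covariate, Acp36DE and Spn77Bb were no longer called (limma adjusted p = 0.22 and 0.54). Acp36DE is itself on the accessory gland list that the covariate is made from, so the loss of its call says little. Without day 5 all of these genes kept their calls, but the slopes of Mst98Cb, Mst57Dc and aqrs were -0.29, -0.20 and -0.16. With quantile normalization those of Acp36DE and Spn77Bb were -0.059 and -0.089.

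Over both genotypes 4798 units changed with age, 1926 rising and 2872 falling. The excess of falls was not stable: the split was 2385 rising and 2457 falling with quantile normalization, 1511 and 1427 without day 5, and 1029 and 783 with the marker covariate. The covariate itself was lower at day 80 than at day 5, so it takes up part of the falls. Energy metabolism fell as a group: 20 of 21 complex I genes, 8 of 8 in complexes II and III, 8 of 8 in complex IV and 13 of 13 in ATP synthase fell over all genes. Their median slopes were -0.11, -0.17, -0.14 and -0.18 (camera adjusted p = 6.6e-22, 1.5e-16, 1.8e-11 and 3.1e-22, and adjusted p = 0.00012, 0.00029, 0.0017 and 0.00012 with an estimated correlation). ATPsynbeta fell by 0.22, UQCR-Q by 0.25 and SdhC by 0.20. Part of this fall lay between days 5 and 10. Complex I array medians averaged 0.84 in controls at day 5, 0.33 at day 10 and -0.26 at day 80. In Indy206 they averaged 0.69, 0.40 and -0.21. For ATP synthase the averages at these ages were 1.20, 0.28 and -0.45 in controls, and 1.01, 0.51 and -0.42 in Indy206. Between days 10 and 80 the control averages did not fall steadily. At days 20, 50 and 70 they were 0.35, 0.29 and -0.053 for complex I and 0.41, 0.17 and -0.24 for ATP synthase. In Indy206 the averages at days 20, 50 and 70 were 0.21, 0.074 and -0.23 for complex I and 0.21, -0.13 and -0.39 for ATP synthase. In the TCA cycle 9 of 12 genes fell, with a median of -0.072 (camera adjusted p = 2.3e-09), among them mAcon1 at -0.21 and Ogdh at -0.21, and in glycolysis 9 of 10, with a median of -0.10 (camera adjusted p = 1.9e-10), among them Ald1 at -0.16. Both lists were called with an estimated correlation (adjusted p = 0.0024 and 0.0023). Among muscle markers 10 of 17 fell and 4 rose, with a median of -0.080 (camera adjusted p = 0.00055, adjusted p = 0.058 with an estimated correlation). The muscle list was not called without day 5 (median -0.035, camera adjusted p = 0.19): its array medians averaged 1.10 in controls at day 5, 0.35 at day 10 and 0.098 at day 80, and 1.09, 0.37 and 0.30 in Indy206. Midgut enzymes fell in 20 of 26 genes, with betaTry at -0.21 (camera adjusted p = 7.2e-10, adjusted p = 0.034 with an estimated correlation), with a median of -0.14, or -0.071 with the marker covariate.

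Proteasome subunits and some inducible heat shock proteins rose with age. Of 25 proteasome subunits 24 rose, with a median of 0.063 and Rpt3 at 0.11 (camera adjusted p = 1.6e-18, adjusted p = 0.0082 with an estimated correlation). Of 7 measured inducible heat shock proteins, none of them an Hsp70 gene, 4 rose. These were Hsp68 at 0.13, l(2)efl at 0.22, Hsp26 at 0.089 and stv at 0.090. The list median was 0.089 (camera adjusted p = 8.2e-05, adjusted p = 0.0082 with an estimated correlation). Of 27 glutathione S-transferases 10 rose and 2 fell, led by GstD3 and GstD5 (0.23), with a median of 0.019 (camera adjusted p = 0.00011, adjusted p = 0.14 with an estimated correlation). Smaller shifts were called for cytochrome P450 genes, 34 of 79 lower and 8 higher (camera adjusted p = 0.0013, adjusted p = 0.12 with an estimated correlation), and mitochondrial ribosomal proteins, 17 of 60 lower and 2 higher (camera adjusted p = 0.00043, adjusted p = 0.32 with an estimated correlation). Fatty acid oxidation genes fell in 3 of 8 (camera adjusted p = 0.022, adjusted p = 0.26 with an estimated correlation) and cytosolic ribosomal proteins moved up by a median of 0.019 (camera adjusted p = 0.031, adjusted p = 0.51 with an estimated correlation). Without day 80 the lists of fatty acid oxidation and of both kinds of ribosomal protein were not called. Testis markers (median -0.11, 5 of 9 falling) and accessory gland markers (median -0.088, 5 of 11 falling) were called down (camera adjusted p = 0.0020 and 0.00078, adjusted p = 0.26 and 0.18 with an estimated correlation), but neither was called with quantile normalization, where the accessory gland median was 0.0045, or without day 5 (camera adjusted p = 0.19 and 0.061). With the marker covariate, which is made from these lists, the medians were 0.016 and 0.021.

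Taken by genotype, 1655 units changed with age in controls, 890 rising and 765 falling, and 3702 in Indy206, 1420 rising and 2282 falling. Of the rises 735 were shared where 66.2 would be shared by independent lists, and of the falls 569 where 91.5 would be, while 1 unit moved opposite ways. Across all 19077 units the 2 slopes had a Pearson correlation of 0.82, and units are not independent replicates. The test of the difference itself called 0 units with limma. At an unadjusted p under 0.05 there were 1065, where chance alone would pass a share of 0.05 of the 19077 units. The smallest adjusted p was 0.22, for CG9498, with slopes of 0.018 in controls and -0.14 in Indy206. FeCH had slopes of 0.065 and 0.14 and the neprilysin gene Nep6 slopes of -0.0031 and -0.10, and neither was called. With array quality weights CG9498, FeCH and Nep6 were called (limma adjusted p = 0.050 for each), and CG9498 or FeCH also without some single arrays. The count of the difference was 23 without control day 10 replicate 1. Among the 4798 units called over both genotypes, 71.2% had the larger slope in Indy206, with a median size of 0.060 against 0.045 in controls, a share that was not tested. The larger count in Indy206 is not shown to be a difference between genotypes by the tests of single units. Without day 5 the counts were 1283 in controls and 1940 in Indy206, and with the marker covariate their order turned, with 1332 in controls and 956 in Indy206. That covariate was lower at day 80 than at day 5 in both genotypes. It thus takes up part of the change with age, and the turned order cannot be read as a result about the genotypes. With quantile normalization the Indy206 calls split into 1895 rising and 1865 falling, and without Indy day 5 replicate 1 they were 2417.

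**Figure D4:**
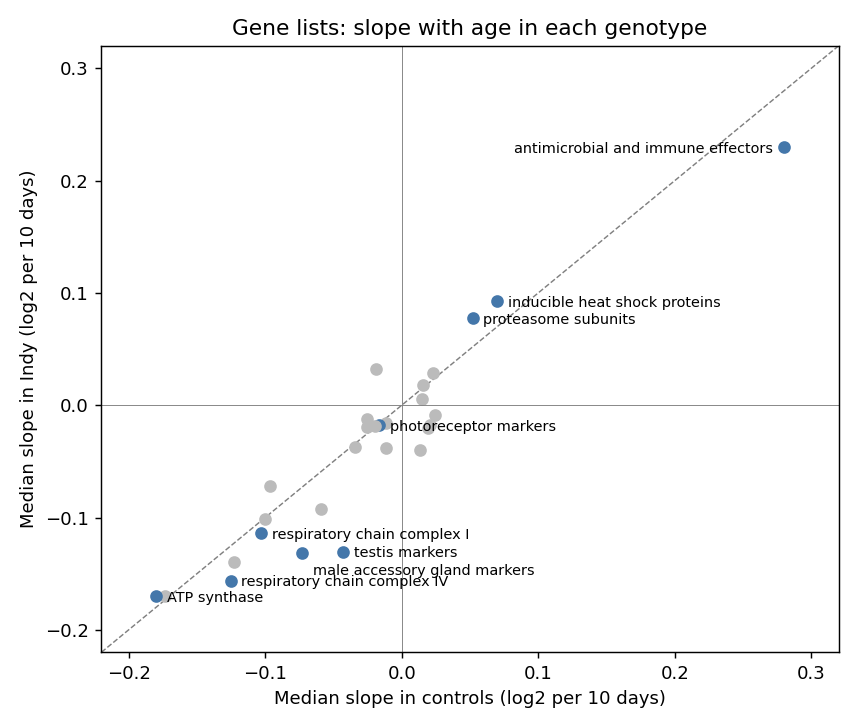
Median slope with age of the 28 gene lists in controls (horizontal axis) and in Indy206 flies (vertical axis), both in log2 units per 10 days, with a dashed line where the slopes are equal. Antimicrobial and immune effectors lie at 0.28 and 0.23, and ATP synthase at -0.18 and -0.17.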

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

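Tests of the explanations below were chosen only after the results were seen, while the splits were set before their outcome was known, that of the respiratory chain lists on lists already seen to differ. No group held 4 or more arrays, so single arrays were not tested for lying far from their group.

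Accessory gland, testis, proteasome and cytochrome P450 lists had slopes that differed between the genotypes by a test of the difference. The median of Indy206 minus control slopes was -0.11 for accessory gland markers, -0.10 for testis markers, 0.031 for proteasome subunits and -0.011 for cytochrome P450 enzymes. Their camera adjusted p-values were 0.011, 0.019, 9.1e-06 and 0.019, and with an estimated correlation adjusted p was 0.61 for each. Relabelling the arrays within ages gave 4 or more lists in 37 of 100 splits, the real one included, with up to 12, so chance is not excluded. For the difference in slope of units the real count was 0, which any split reaches, so the splits decide nothing there. The highest of the 100 had 5 calls.

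For the other counts the splits gave these results. The 67 genotype calls were reached by 1 of 100 splits, the real one, with 1 call as the highest other, so a chance assignment of arrays is excluded for that count. The 8 gene lists called for genotype were reached by 10 of 100 splits, with up to 13, so chance is not excluded. The 1 list called with an estimated correlation was reached by 5 of 100, with 1 as the highest other, so chance is not excluded there either. Shuffling ages within each genotype gave at most 230 calls against 1655 in controls, 760 against 3702 in Indy206 and 138 against 4798 over both, and only the real order of 100 reached the count in each case (1 of 100). The 10 splits of 6 arrays at single ages are too few for a share under 0.05. They gave the real 9 calls at day 30 against a highest other of 54 (3 of 10 as large), 3 against 1 at day 50, 26 against 9 at day 70 and 6 against 1 at day 80 (1 of 10 each).

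The first pattern is the low level of respiratory chain and ATP synthase transcripts in Indy206, though the lists were not lower at days 10 and 80. Averaged over ages, 48 of 50 genes lay below 0 with a median of -0.13. Only the real labelling of 100 gave a median as far from 0 (1 of 100, highest other -0.097), but these lists were singled out after the results of 28 lists were seen, which this count does not allow for. Less muscle of all kinds in the samples is argued against by the flight and body muscle markers, whose array median differed by 0.018 with a 95% interval above -0.1. That list mixes flight muscle genes with those of other muscle, so it cannot exclude less flight muscle alone. A difference in abdominal markers between arrays is argued against too, since the median was -0.13 with the marker covariate and complex I was still called (adjusted p = 3.8e-09). An older expression state cannot be told apart: genotype difference and age slope correlated at 0.27 across 4798 units, 37 of 100 splits were as high, and the splits ranged from -0.66 to 0.66. The cause is left open.

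The second pattern is the low level of testis and accessory gland transcripts against the reference. Over the control arrays the mean linear ratio had a median of 0.234 over 20 markers, against 1.64 for photoreceptor markers, although a pool of these same RNAs would give about 1. If the ratio is sample over reference, this is consistent with reference RNA that holds more abdominal tissue than the samples, a candidate explanation that the labels do not state. Not every such transcript was low throughout: in controls at day 5 Mst98Cb stood at 0.27, Mst57Dc at -0.049 and aqrs at -0.052, and the testis list at -1.16. These genes were named for their steep fall with age, and others were low at day 5 too. Acp36DE stood at -2.72 and Spn77Bb at -1.99, and the accessory gland list at -1.77 and -1.45 on the 2 control arrays. Dye bias of single spots is argued against as the whole cause: 18 of 20 markers lay below 0.5 of the reference, a share 9.59 times that of other genes, and turning the ratio mirrors both shares alike.

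The third pattern is that genes called for genotype lie near each other. Of 50 such genes, 19 had another within 10 measured neighbours, against a mean of 4.71 in 10000 random draws (share as high 2e-04), so chance placement is argued against. A local effect of the altered Indy gene is argued against, as 0 of the 19 lie within 50 measured genes of Indy. Cross-hybridisation between neighbouring copies is argued against as the whole cause, as 5 of 14 pairs moved opposite ways, such as CG15818 at 1.66 and CG5958 at -0.50. The pairs are not independent, since CG5160, CG15818, CG5958 and Cyp4d21 lie together and share several of them. Whether the genes of a pair are copies of each other was not checked. Differences between the 2 fly lines at other loci may contribute, and the design does not separate them from Indy itself; they were not tested.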

How the results depend on the processing

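The alternatives were set before the data were examined, except the 1-gene, marker covariate and 2-array ones, chosen after seeing the data. The filters on missing values were not run, since no value is missing. The Indy difference was -0.88 with median-centred arrays and -0.91 to -0.85 with each array left out. Genotype calls were 24 with a minimum size and 46 to 95 with each array left out. Calls summed over ages were 148 (quantile), 123 (array weights) and 2 (ages alone), and 39 to 163 with each array left out. Control slopes gave 1077 without day 80, and 1174 to 1797 with each array left out. Indy206 slopes gave 1940 without day 5 and 956 with the marker covariate, and 2417 to 3888. Slopes over both gave 2938 without day 5, 2557 with a minimum size and 1812 with the covariate, and 4006 to 5128. Slope differences gave 4 with array weights, and 0 to 23 (23 without control day 10 replicate 1). Lists called for genotype were 1 with an estimated correlation and 5 with fry (7 to 10 with each array left out), and for each slope 10 with an estimated correlation. Left-out ranges were 15 to 19 (controls), 15 to 18 (Indy206) and 17 to 19 (both). Lists called for the slope difference were 1 (quantile, common spread and linear regression), 11 (without day 80), 2 (without day 5, 1-gene spots, marker covariate) and 0 (estimated correlation, fry), and 1 to 6. The median accessory gland slope turned to 0.0099 (quantile), 0.0043 (without day 5) and 0.019 (covariate) in controls, 0.021 (quantile) and 0.029 (covariate) in Indy206, and 0.0045 (quantile) and 0.021 (covariate) over both. The median testis slope turned to 0.0052 (quantile), 0.0021 (without day 5) and 0.034 (covariate) in controls, and with the covariate to 0.011 in Indy206 and 0.016 over both, and the ATP synthase slope difference to -0.033 without day 80. A minimum size leaves fewer calls by construction, and no other cause was tested. Named genes kept their direction in all settings, and CG9498, FeCH and Nep6 gained a call for the slope difference with array weights (limma adjusted p = 0.050). The replicate block changed none of the counts over ages by over 1.5 times: with number as a term 69, 1682, 3526 and 4761 units were called for genotype, control, Indy206 and joint slopes, and with a random block 79, 1660, 3709 and 4547. At day 20 the block gave 1 and 5 calls against 0. The numbers were not taken to pair the samples, as the correlations of pairs of equal age and number ran from -0.35 to 0.62. Of 19 such pairs 13 lay over 0.1, and the 2 at day 10 hold the same value, since groups of 2 arrays mirror each other. The mean over the pairs, 0.13, lies above the -0.016 of other groups and numbers, and day 50 gave 0.36 to 0.62. A shared origin at some ages is therefore not excluded. A control day 70 array is replicate 3 in its title, used here, and 1 in its description. Where a group of 2 loses an array, the lone one is assumed to vary like other groups. Signal over background limits low spots and was not analysed here.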

Other observations

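These genes and lists were picked out after the results were seen. The remaining lists showed no call for age over both genotypes, though single members moved. Photoreceptor markers had a median slope of -0.025 (camera adjusted p = 0.24), with 3 of 15 falling and 1 rising, led by the arrestin gene Arr1 at -0.12. Haemocyte markers had a median of 0.0080 (camera adjusted p = 0.96), where the prophenoloxidase genes PPO1 and PPO2 fell by 0.24 and 0.16 while crq rose at 0.092. Circadian clock genes had a median of -0.026 (camera adjusted p = 0.48), with per and cry falling by 0.036 and 0.066. Antioxidant enzymes had a median of -0.0092 (camera adjusted p = 0.64), where the mitochondrial Sod2 fell by 0.088 and 3 others rose. Insulin and FOXO genes had a median of 0.0037 (camera adjusted p = 0.17), with Akt rising at 0.095. Fatty acid synthesis genes had a median of -0.011 (camera adjusted p = 0.88), neuron markers one of -0.019 (0.10), odorant-binding proteins one of -0.021 (0.61), fat body markers one of -0.011 (0.60) and yolk proteins one of 0.0052 (0.64). Some of these depend on the processing. Neuron markers were called down with quantile normalization, with array weights, without day 5 (median -0.032, camera adjusted p = 0.0058) and with the marker covariate (-0.037, camera adjusted p = 0.0011). Photoreceptor markers were called down with the marker covariate (-0.042, camera adjusted p = 0.00014), and clock genes without day 5 (-0.039, camera adjusted p = 0.038). With fry, the neuron, photoreceptor, clock and fat body lists were called down and the insulin and FOXO list up.

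For genotype, the lists without a call included TCA cycle genes at a median of -0.064 and inducible heat shock proteins at 0.025, both with a camera adjusted p of 0.055. Both were called with the replicate number as a term (camera adjusted p = 0.045 each) and without days 5 and 10, where the TCA median was -0.16 (camera adjusted p = 0.0023) and the heat shock median 0.057 (camera adjusted p = 0.047). TCA genes were also called with no interaction, and heat shock proteins with quantile normalization (median 0.072, camera adjusted p = 0.036), a common spread, array weights and without the 2 arrays that stand apart, and both lists without some single arrays. Accessory gland markers, at 0.095, were called with a common spread (0.29, camera adjusted p = 0.011), and glutathione S-transferases with array weights (-0.024, camera adjusted p = 0.049) and without control day 10 replicate 2 or control day 30 replicate 1. Adjusted over the list alone, l(2)efl at 0.39 and Hsp26 at 0.20 passed, as did Idh3a at -0.18 in the TCA cycle. Fatty acid synthesis genes had a median of -0.064, with AcCoAS at -0.21 passing adjusted over the list alone. Antimicrobial effectors had a median of -0.010 while the test pointed up (camera adjusted p = 0.67). Among midgut enzymes LysP at -0.39 passed adjusted over the list alone. Among spots without a paired gene, spot 6915 was higher in Indy206 by 1.54 ± 0.067 (SE, limma adjusted p = 7.7e-16), the smallest p of the genotype comparison. Called genes lower at 7 of 8 ages include smp-30 at -0.76 ± 0.12 (SE), veil at -0.67 ± 0.12 (SE) and the galactokinase gene Galk at -0.43 ± 0.082 (SE).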
